A study of Caenorhabditis elegans with 6 samples.

How the data were processed

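Whole third-stage (L3) larvae of the Caenorhabditis elegans wild-type strain N2 were profiled by poly(A)-selected, paired-end mRNA sequencing, per the labels' protocols. Animals were fed from hatching on Escherichia coli HT115, a strain that makes double-stranded RNA for feeding RNA interference (RNAi). The bacteria carried the empty vector L4440 (EV) or a clone against grd-1 from the Ahringer library. Each group had 3 libraries, which the labels describe as independently synchronized animals grown on independent bacterial cultures. All 6 libraries stand in 1 batch on the deposited sample sheet.

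The submitters' processing notes name Salmon, STAR, DESeq2, FastQC and MultiQC and the builds WBcel235 and ce11, without versions or roles. The authors deposited an estimated count per gene for each library, as made by Salmon per the submitters' processing notes, with no normalization. These values were not whole in 20.5% of cells. For 21896 of the 21982 genes the deposited estimated count could be rebuilt by summing the Salmon transcripts of the gene, and in 0 of them did the sum differ by more than 0.5 counts in any library. Per the file headers, the deposited Salmon tables also give TPM, an abundance relative to all transcripts of the library, for 35749 transcripts, which are scaled to the same sum in every library and keep no depth. The deposited sample sheet gives the count of sequenced reads, a quality score and an RNA integrity score per library, and the percent of bases at high quality and of RNA fragments over the DV200 length. How the sample sheet's values were made is not given in the sources used here. Whether counting used strand is not given either, so reads of overlapping genes on opposite strands cannot be told apart.

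A table of raw whole-number counts had been planned for. Because the table held estimated counts, these were rounded to whole numbers before testing, which the design had allowed for. Gene symbols and positions came from the Ensembl 115 annotation of WBcel235, which is newer than the transcript names in the deposited tables, and 19793 genes had a symbol. Of the Salmon counts, 0.0192% to 0.0409% per library lay on transcripts with no gene in that annotation. The total count per library ran from 19505838 to 28283822, or 84.0% to 92.6% of the sequenced reads listed. Genes were kept by filterByExpr at a minimum count of 10, which left 13274.

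Counts were normalized by trimmed mean of M values (TMM) and tested with edgeR 4.0.16 by a quasi-likelihood F test (glmQLFit, glmQLFTest) of the libraries labelled grd-1 RNAi against EV, without covariates, in R 4.3.3. All tests were two-sided except Fisher's exact test and the count of neighbouring genes, which were one-sided for an excess. The Benjamini-Hochberg method was used at an adjusted p of 0.05. CPM values are counts scaled by the TMM-adjusted library totals. Log2 fold changes are those of the fit with their standard errors (SE), and other errors are SDs over 3 libraries. For grd-1, a single planned gene, the unadjusted p was the criterion, and the adjusted p is given beside it. With 3 libraries in each group an exact permutation test of a single value cannot go below p = 0.1.

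There were 43 gene lists, fixed before the data were examined and matched to whole gene symbols. They cover hedgehog-related and cuticle genes, larval timing, tissues, and metabolic, stress and small-RNA genes. They were tested with camera of limma 3.58.1 on the edgeR data at a preset correlation between genes of 0.01, with grd-1 left out of every list. Alternatives with an estimated correlation and with fry were run beside it. Genes were named by a rule fixed before the data were examined. It named grd-1, ptr-11, nhr-23, lin-42, lin-29 and mlt-10 whatever their values, and then the 8 largest rises and 8 largest falls past the threshold at a mean CPM of at least 1 with groups that did not overlap. With none past it, the rule named the 4 genes with the smallest p in each direction. It also named up to 3 called members of each list. All other genes in the text were chosen after their values were seen, mostly from the DESeq2 calls.

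The alternatives fixed before the data were examined were DESeq2 size factors or library totals in place of TMM, DESeq2 1.42.0 and limma-voom as tests, no filter or at least 50 counts in 3 libraries, the replicate number as a block, each library left out in turn, Salmon transcript sums, a robust fit, and a fold threshold of 1 on the log2 scale. Average transcript length as an offset, DESeq2 with each library left out, Fisher's exact test on the DESeq2 calls and 4 further gene lists were added after seeing the data. DESeq2 was fitted to all 21982 genes without the filter on low counts, unlike the main edgeR fit and limma-voom. Adjusted p-values that DESeq2 left as missing stayed missing, so its counts refer to 12988 genes.

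The tests were tested on simulated data, drawn for the 13274 tested genes from the means, dispersions and library sizes of the grd-1 RNAi and EV comparison with 200 genes changed. In that simulation edgeR recovered 64% of the 2-fold and 96% of the 4-fold changes, with 12 false calls among 172. DESeq2 recovered 69% and 94%, with 29 false calls among 192. The real DESeq2 fit also took in genes below the filter, which the simulation did not hold. With nothing changed, edgeR made 1 call, DESeq2 made 15 and limma-voom made 0. Each gene was drawn independently of the others, without the variation that genes share between the real libraries. These shares therefore do not say how many real changes were missed. In the real data edgeR did not call grd-1, at 6.49-fold (edgeR adjusted p = 0.0920 over all tested genes). In camera a list of 30 genes raised by 0.3 on the log2 scale was called, and 0 of 10 unchanged lists were called. The simulated genes were uncorrelated, so this did not test camera on lists whose genes vary together. In the real data the estimated correlation was 0.289 in the germline list and 0.452 in the oocyte and eggshell list.

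Replicate libraries of a group were compared by a chi-square statistic over genes. It lay between 21.3 and 80.7 per degree of freedom, so no library held the values of another library of its group deposited again. That the libraries are independent replicates rests on the labels. Tables were joined and figures drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. Sequence reads and a genome sequence were not used here, so coverage along a gene was not analysed.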

Results

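The transcriptomes of L3 larvae fed from hatching on bacteria with the empty vector (EV) or with a clone producing grd-1 double-stranded RNA were measured by mRNA sequencing, with 3 libraries in each group. The series asks what reduction of grd-1, a secreted protein of the groundhog family related to hedgehog, does to larval gene expression. Total estimated counts were 22728434, 19505838 and 22296119 in EV replicates 1, 2 and 3. They were 20917930, 21857551 and 28283822 in replicates 1, 2 and 3 of the libraries labelled grd-1 RNAi. EV replicate 1 had an RNA integrity number of 8.3, and the other libraries had 10. Correlations of log2 CPM over genes were 0.974 to 0.988 within groups and 0.97 to 0.989 between groups.

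The targeted gene was higher, not lower, in the libraries labelled grd-1 RNAi. The grd-1 transcript (WBGene00001690, chromosome X, 11109440 to 11115887, plus strand, WBcel235, protein-coding) averaged 8.71 ± 2.28 CPM in EV and 56.8 ± 19.2 CPM in the libraries labelled grd-1 RNAi (SD, n = 3 each). The fitted difference was 2.70 on the log2 scale (SE 0.275), or 6.49-fold. EV replicates 1, 2 and 3 had 7.28, 7.50 and 11.3 CPM, and the libraries labelled grd-1 RNAi had 77.9, 51.96 and 40.4 CPM, so the groups did not overlap. The unadjusted p of the edgeR quasi-likelihood test was 6.93e-06, and the edgeR adjusted p was 4.16e-05 over the 6 genes named in advance and 0.0920 over all tested genes. DESeq2 gave an adjusted p of 6.77e-19. Summed over transcripts, the deposited Salmon level was 1.58 ± 0.553 TPM in EV and 10.4 ± 3.21 TPM in the labelled libraries (SD, n = 3, two-sided exact permutation p = 0.1, the smallest that 3 libraries against 3 allow). Of the 5 other genes tested within 20 kb, the median log2 fold change was -0.03, and the gene nlp-66, chosen after its value was seen, had 0.03 (SE 0.364), with values from -0.16 to 0.33 when a library was left out. A gene total does not separate reads of the worm's own mRNA from reads of the fed double-stranded RNA. Because the targeted gene runs against the label, every direction given here is a direction between labels.

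**Figure D1:**
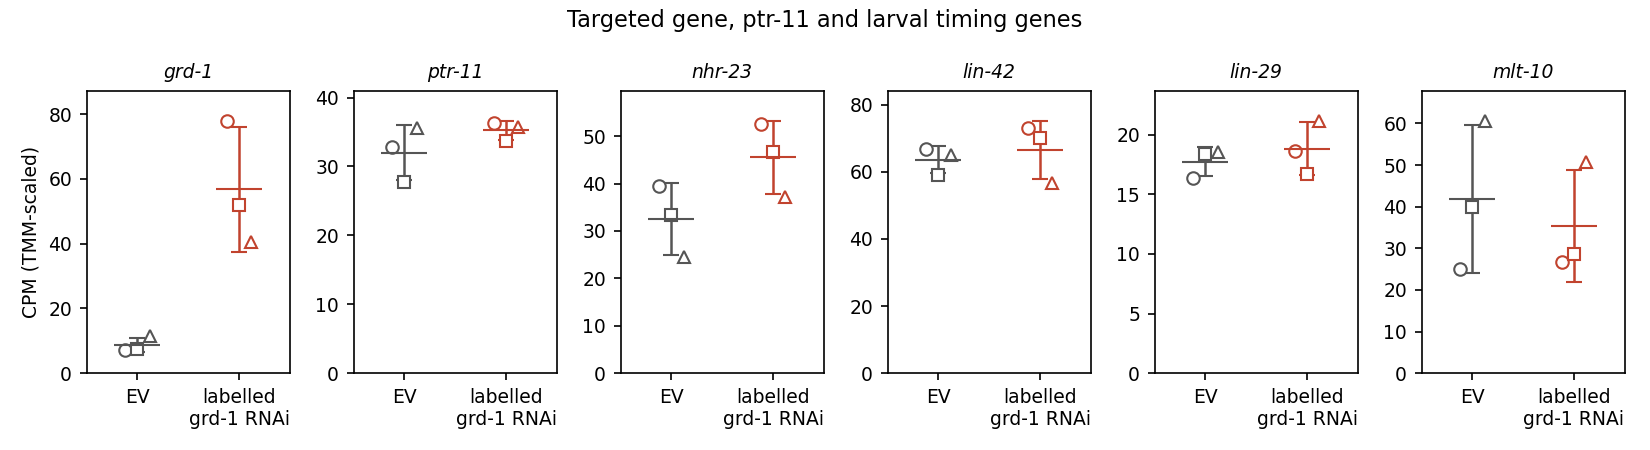
CPM (TMM-scaled, linear axis from 0) of grd-1, ptr-11, nhr-23, lin-42, lin-29 and mlt-10 in EV libraries (grey) and libraries labelled grd-1 RNAi (red), with an open symbol per library (circle, square and triangle for replicates 1, 2 and 3), a horizontal line at the mean and whiskers of 1 SD. The lowest labelled library for grd-1, at 40.4 CPM, lies above the highest EV library, at 11.3 CPM, while the groups overlap for the other genes.

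Without a replicate block, genes of larval timing and molting and the patched-related gene ptr-11 did not pass the edgeR, DESeq2 or limma-voom threshold. The comparison was between EV and the libraries labelled grd-1 RNAi. The patched-related transcript ptr-11 (WBGene00004225, chromosome I) had 32.0 ± 3.98 CPM in EV and 35.2 ± 1.38 CPM in the labelled libraries (SD, n = 3), a log2 fold change of 0.14 (SE 0.118, edgeR adjusted p = 0.750). For nhr-23, a nuclear hormone receptor required for molting, the levels were 32.5 ± 7.54 and 45.5 ± 7.74 CPM, a log2 fold change of 0.49 (SE 0.192, edgeR adjusted p = 0.571). With the replicate number as a block nhr-23 had 0.50 (SE 0.1) and passed the threshold (edgeR adjusted p = 0.0168). Whether the numbers pair the libraries is not stated. The period-related timing gene lin-42 had a log2 fold change of 0.06 (SE 0.121), and lin-29, a zinc finger factor of the larval-to-adult switch, had 0.09 (SE 0.130). The molting gene mlt-10 had -0.24 (SE 0.338), and its CPM ran from 25.1 to 60.6 within EV alone. The signs of lin-42, lin-29 and mlt-10 each turned when 1 library was left out. The values were -0.01 for lin-42 without grd-1 RNAi replicate 1, -0.01 for lin-29 without grd-1 RNAi replicate 3 and 0.12 for mlt-10 without EV replicate 3.

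Across all genes, the smallest p-values apart from grd-1 belonged to pud-3, pud-4, cyp-35A3 and asm-3 in the upward direction and to F21C10.9, H20E11.2, ugt-44 and F22B8.7 in the downward direction, none past the edgeR threshold. The pud genes encode proteins first described as upregulated in insulin receptor (daf-2) mutants. The pud-3 transcript had 91.4 ± 12.9 CPM in EV and 190.4 ± 16.3 CPM in the libraries labelled grd-1 RNAi (SD, n = 3), a log2 fold change of 1.06 (SE 0.133). Its neighbour pud-4 had 33.8 ± 8.42 and 68.3 ± 4.60 CPM, a log2 fold change of 1.01 (SE 0.177). Both lie on chromosome V, pud-3 at 2324634 to 2325152 and pud-4 at 2326678 to 2327282. The cytochrome P450 gene cyp-35A3 had 1.66 ± 0.661 and 5.37 ± 0.543 CPM, a log2 fold change of 1.70 (SE 0.282). For asm-3, an acid sphingomyelinase, the log2 fold change was 0.79 (SE 0.151). In the other direction, F21C10.9 (chromosome V, 9097201 to 9098696) had 161.7 ± 45.8 CPM in EV and 43.9 ± 12.2 CPM in the labelled libraries, a log2 fold change of -1.88 (SE 0.245). The log2 fold change was -1.59 (SE 0.211) for H20E11.2 on chromosome IV and -0.74 (SE 0.102) for F22B8.7 on chromosome V. The UDP-glycosyltransferase gene ugt-44 on chromosome IV had 98.8 ± 10.98 and 48.2 ± 7.12 CPM, a log2 fold change of -1.03 (SE 0.139). For each of these 8 genes all 3 labelled libraries lay beyond all 3 EV libraries, and the edgeR adjusted p lay between 0.152 for pud-3 and 0.257 for asm-3.

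Of 13274 genes tested, edgeR called 0 at an adjusted p of 0.05, with 0.092 for grd-1 as the smallest. At an unadjusted p of 0.05 there were 1139 genes, 470 higher and 669 lower in the labelled libraries, where chance gives 663.7 on average. In 2090 genes, or 15.7% of those tested, the groups did not overlap, where chance gives 10% on average. Genes vary together, so such counts spread widely around these means. Other splits of the 6 libraries gave 78 to 3303 genes at an unadjusted p under 0.05, and 3 splits gave as many as the real one, itself included. Neither count is thus shown to exceed chance. limma-voom called 0 genes. DESeq2, fitted to all genes without the filter on low counts, called 79, of which 13 were higher and 66 lower in the labelled libraries. All 79 had the same sign and an unadjusted p under 0.05 in edgeR, and in all 79 the groups did not overlap. Both tools used the same counts, so this is not separate support for the calls. Without any filter on low counts edgeR called 5 genes, which were grd-1, pud-3, F21C10.9, H20E11.2 and ugt-44, and without grd-1 RNAi replicate 3 it called 1, grd-1. With the replicate number as a block edgeR called 416 genes (99 higher, 317 lower). Whether the numbers pair the libraries is not stated. The DESeq2 count was 42 (7 higher, 35 lower) without grd-1 RNAi replicate 1, 34 (11 and 23) without replicate 2 and 45 (9 and 36) without replicate 3 of that group. It was 109 (34 and 75) without EV replicate 1 and 56 (17 and 39) without EV replicate 2.

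**Figure D2:**
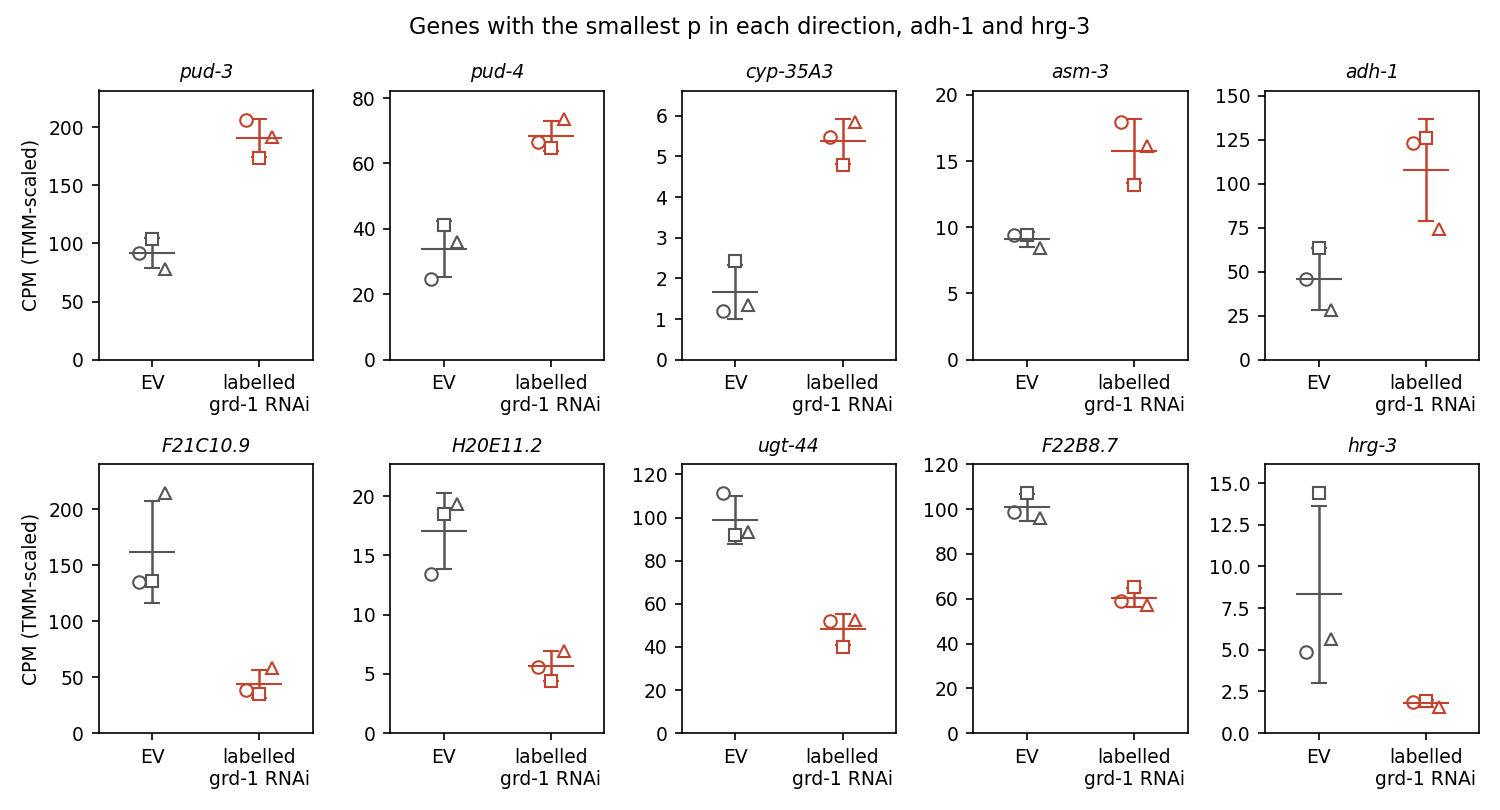
CPM (TMM-scaled, linear axis from 0) of the 4 genes with the smallest p in each direction apart from grd-1, and of adh-1 and hrg-3, chosen after their values were seen, in EV (grey) and the libraries labelled grd-1 RNAi (red), with an open symbol per library, a horizontal line at the mean and whiskers of 1 SD. In all 10 genes the groups do not overlap, for example 78.2 to 103.9 CPM in EV and 173.5 to 205.9 CPM in the labelled libraries for pud-3.

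The genes past the DESeq2 threshold included argk-1, cth-1, gpdh-1, asp-12, cpr-1 and adh-1, with directions again between labels. These genes were chosen after their values were seen. Lower in the libraries labelled grd-1 RNAi were argk-1, an arginine kinase, at a log2 fold change of -1.13 (SE 0.176), and cth-1, a cystathionine gamma-lyase, at -0.93 (SE 0.144). Their DESeq2 adjusted p-values were 3.93e-06 and 2.51e-05. The glycerol-3-phosphate dehydrogenase gene gpdh-1 had -0.74 (SE 0.127), the infection response gene irg-2 had -1.85 (SE 0.463), and the uncharacterized genes C49G7.7 and C49G7.10 had -1.91 (SE 0.319) and -1.22 (SE 0.219). Higher in those libraries were the protease genes asp-12 and cpr-1, at 1.34 (SE 0.267) and 0.82 (SE 0.201), and the alcohol dehydrogenase gene adh-1, at 1.23 (SE 0.301). The edgeR adjusted p of these genes lay between 0.205 for argk-1 and cth-1 and 0.391 for irg-2. The value for irg-2 was -1.24 without EV replicate 1. In the 6 DESeq2 fits with a library left out, argk-1, cth-1, C49G7.7, C49G7.10 and asp-12 were called in all 6, and gpdh-1, irg-2, cpr-1 and adh-1 in 3.

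Fasting-induced lipid breakdown genes and oxidative and xenobiotic response genes, from lists fixed in advance, held more DESeq2 calls than independent draws would give. The test was chosen after the results were seen. It takes genes as independent and does not measure the spread between libraries. Of 47 fasting-induced lipid breakdown genes 5 were called, where 0.282 were expected (one-sided Fisher's exact test for an excess over 12987 genes, adjusted p = 0.00029 over the 43 lists). The acyl-CoA dehydrogenase gene acdh-1, at a log2 fold change of -1.26 (SE 0.265), the hydroxyacyl-CoA dehydrogenase gene hacd-1, at 53.9 ± 34.5 CPM in EV and 13.5 ± 2.71 CPM in the labelled libraries, and the lipid-binding protein genes lbp-3 and lbp-4, at -0.58 (SE 0.127) and -0.52 (SE 0.0961), were lower in the libraries labelled grd-1 RNAi, and cpt-5 was higher at 0.98 (SE 0.251). The log2 fold change of hacd-1 was -1.33 without EV replicate 1, which had 93.7 CPM against 34.9 and 33.1 CPM in the other EV libraries. Of 183 oxidative and xenobiotic response genes 8 were called, where 1.1 were expected (adjusted p = 0.00029). The P450 genes cyp-35A3 and cyp-35C1 were higher, the second at 1.01 (SE 0.247), and cyp-33C8, gst-22, ugt-2, ugt-43, ugt-44 and ugt-54 were lower, from -0.59 for ugt-2 to -1.68 for ugt-43. Of the 6 DESeq2 fits with a library left out, all 6 called cyp-35A3 and ugt-44, 5 called acdh-1 and hacd-1, 4 called ugt-43, 3 called gst-22 and ugt-54, 2 called cpt-5, cyp-35C1 and cyp-33C8, and 1 called lbp-3, lbp-4 and ugt-2. Neither list had a shared direction past the threshold, with camera adjusted p = 0.813 for 48 fasting-induced genes (25 above 0, 23 below) and 0.677 for 190 oxidative and xenobiotic genes (95 above, 95 below). At an unadjusted p under 0.05, 6 fasting-induced genes were higher and 6 lower, and 21 oxidative and xenobiotic genes were higher and 19 lower. Adjusted over the list alone, edgeR called 6 fasting-induced genes and 7 oxidative and xenobiotic genes, and 0 in either over all genes tested. Members of the ugt and cyp families share sequence with close relatives, so their split of reads is uncertain.

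The lists that fell in the libraries labelled grd-1 RNAi were the intracellular pathogen response, neuropeptides and hedgehog-related ligands, by camera at the preset correlation. Of 20 intracellular pathogen response genes, which include the pals family, 15 lay below 0 and 5 above, with a median log2 fold change of -0.34 (camera adjusted p = 9.58e-06, and adjusted p = 0.358 with an estimated correlation). Adjusted over the list alone edgeR called 5 of them, and over all genes tested 0, with 6 lower at an unadjusted p under 0.05 and 2 called by DESeq2. The adjacent genes pals-23 and pals-24 on chromosome III had -0.72 (SE 0.124) and -0.71 (SE 0.110), both past the DESeq2 threshold (in 3 and 5 of the 6 fits with a library left out), and pals-37 had -1.25 (SE 0.323). Of 86 neuropeptide genes 65 lay below 0 and 21 above, with a median of -0.16 (camera adjusted p = 0.000823, and adjusted p = 0.593 with an estimated correlation), and nlp-20 had -0.58 (SE 0.138). This call ended without EV replicate 1 (adjusted p = 0.0668). Of 35 hedgehog-related ligands, counted without grd-1, 30 lay below 0 and 5 above, with a median of -0.31 (camera adjusted p = 0.00112, and adjusted p = 0.634 with an estimated correlation), and the warthog gene wrt-5 had -0.35 (SE 0.114). This call ended without EV replicate 3 (median -0.15, adjusted p = 0.0617), and the median was -0.54 without EV replicate 1. The median hedgehog-related ligand also differed by 0.705 on the log2 scale between EV replicates 3 and 1 and by 0.793 between grd-1 RNAi replicates 3 and 1, more than between the groups. The genes given as examples from these lists were chosen after their values were seen.

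The 10 lists that rose in the libraries labelled grd-1 RNAi had medians from 0.09 to 0.23, and none of the 10 calls held with an estimated correlation. The balance of 10 lists higher and 3 lower was 5 and 5 without EV replicate 2, 7 and 6 without grd-1 RNAi replicate 2, and 15 and 3 without EV replicate 1. Of 39 germline genes 35 lay above 0 and 4 below, with a median of 0.11 (camera adjusted p = 0.00044, and adjusted p = 0.634 with an estimated correlation), and gld-1, an RNA-binding regulator of germ cells, had 0.50 (SE 0.141). Of 18 oocyte and eggshell genes 17 lay above 0 and 1 below, with a median of 0.23 (camera 0.0016, and adjusted p = 0.636 with an estimated correlation), and the eggshell gene cpg-1 had 0.50 (SE 0.168). Of 55 RNA interference genes 45 lay above 0 and 10 below, with a median of 0.14 (camera 0.000762, and adjusted p = 0.495 with an estimated correlation). The Argonaute gene alg-1 had 0.28 (SE 0.0908) and rde-10 had 0.45 (SE 0.143). Of 24 body wall muscle genes 21 lay above 0 and 3 below, with a median of 0.15 (camera 0.00112, and adjusted p = 0.593 with an estimated correlation), and the troponin I gene tni-3 had 0.35 (SE 0.0998). Of 17 heterochronic genes 14 lay above 0 and 3 below, with a median of 0.14 (camera 0.0141, and adjusted p = 0.634 with an estimated correlation). Their members mab-10 and dre-1 had 0.61 (SE 0.200) and 0.34 (SE 0.110). The example genes were chosen after their values were seen. Leaving out single libraries ended none of the calls for germline, RNA interference and body wall muscle. It ended that for oocyte and eggshell without grd-1 RNAi replicate 2 (adjusted p = 0.0642), and that for heterochronic genes without EV replicate 1 (0.261) or grd-1 RNAi replicate 3 (0.068). It moved medians by over 1.5 times in each of these 5 lists. The germline median was 0.23 without EV replicate 1, that of RNA interference genes 0.07 without grd-1 RNAi replicate 3, and that of heterochronic genes 0.07 without EV replicate 1. The oocyte and eggshell median was 0.39 without EV replicate 1 and 0.13 without grd-1 RNAi replicate 2, and the body wall muscle median was 0.09 without either EV replicate 3 or grd-1 RNAi replicate 2. Between EV replicates 3 and 1, median genes of the oocyte and eggshell, germline and heterochronic lists differed by -0.404, -0.227 and 0.315 on the log2 scale, more than between the groups. Between grd-1 RNAi replicates 3 and 1 they differed by -0.193, -0.0502 and 0.215, more than between the groups for heterochronic genes alone.

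The other lists that were higher in the libraries labelled grd-1 RNAi had medians of up to 0.12. The lists of DNA replication and cell cycle (45 of 59 above 0, 14 below), nuclear pore complex (27 of 38, 11 below), intestine (13 of 19, 6 below), pharynx (43 of 65, 22 below) and ribosome biogenesis genes (29 of 37, 8 below) had medians of 0.09, 0.11, 0.12, 0.11 and 0.09. Their camera adjusted p-values were 0.0141, 0.0141, 0.0231, 0.0233 and 0.0418, and with an estimated correlation the adjusted p-values were 0.690, 0.709, 0.634, 0.634 and 0.724. The DNA replication, nuclear pore and ribosome biogenesis calls ended without EV replicate 2 (adjusted p = 0.292 for each) or grd-1 RNAi replicate 3 (0.068, 0.063 and 0.281), and the last also without grd-1 RNAi replicate 2 (0.0511). The intestine call ended without EV replicate 2 (0.0518), EV replicate 3 (0.110), grd-1 RNAi replicate 1 (0.069) or grd-1 RNAi replicate 2 (0.0542). The pharynx call ended without EV replicate 2 (0.133), grd-1 RNAi replicate 2 (0.263) or grd-1 RNAi replicate 3 (0.153). With the replicate number as a block the pharynx and ribosome biogenesis calls also ended (camera adjusted p = 0.0602 and 0.0525). Medians moved by over 1.5 times here too. Without EV replicate 2 they were 0.05 for DNA replication, 0.04 for nuclear pore and 0.08 for pharynx genes. The ribosome biogenesis median was 0.14 without grd-1 RNAi replicate 1 and 0.04 without replicate 3 of that group. The pharynx median was 0.18 without grd-1 RNAi replicate 1 and 0.04 without replicate 2. The intestine median was 0.20 without either EV replicate 1 or grd-1 RNAi replicate 3, and 0.07 without grd-1 RNAi replicate 2. Between EV replicates 3 and 1 the median nuclear pore, intestine, pharynx and ribosome biogenesis genes differed by -0.136, -0.142, 0.0139 and 0.0878, and between grd-1 RNAi replicates 3 and 1 by 0.0641, -0.0908, 0.115 and 0.135. In each of these 4 lists 1 or both of the labels thus differed within itself by about as much as the groups did or more. The intestinal protease gene cpr-1 was the member of these lists that passed the DESeq2 threshold.

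**Figure D3:**
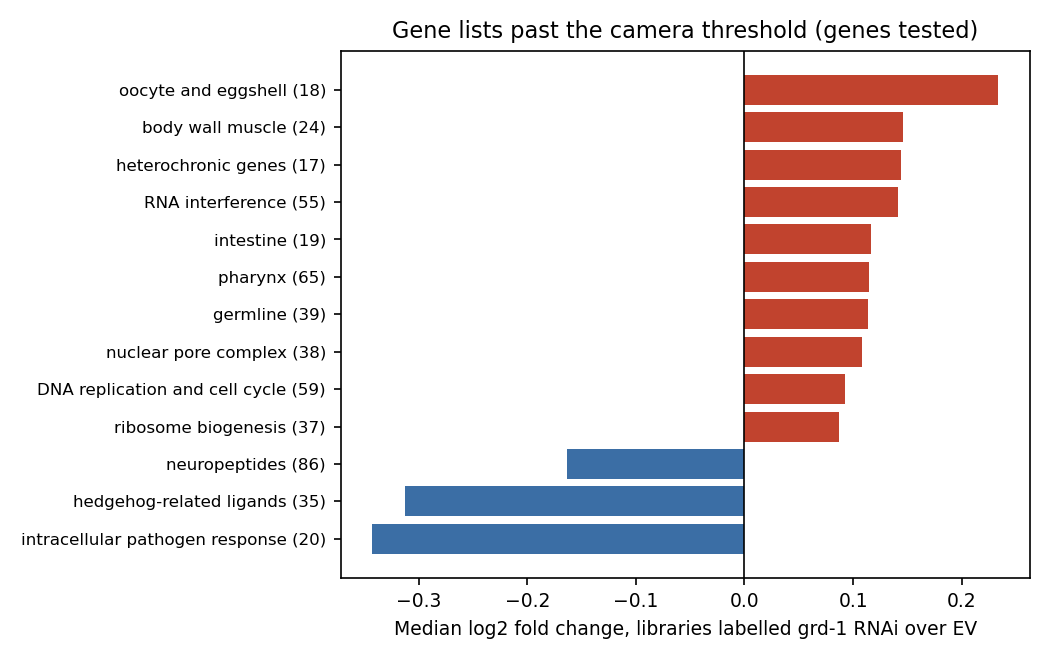
Median log2 fold change (x axis, libraries labelled grd-1 RNAi over EV) of the 13 gene lists past the camera threshold at the preset correlation, with the number of tested genes in brackets. Medians run from -0.34 for the intracellular pathogen response to 0.23 for oocyte and eggshell genes, and none of the 13 is past the threshold with an estimated correlation.

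The other 30 lists did not pass the camera threshold. Among genes of the cuticle and the molt, 62 of 133 cuticle collagens lay above 0 and 71 below, all 6 furrow collagens above, and 3 of 12 other body-shape collagens above and 9 below (camera adjusted p = 0.159, 0.159 and 0.0545). Of 27 molting factors 16 lay above and 11 below, of 54 cuticlins and matrix ZP proteins 33 and 21, of 12 molting clock regulators 9 and 3, of 11 seam cell genes 7 and 4, and of 16 genes of the vulva and ventral epidermis 11 and 5 (0.0541, 0.256, 0.0807, 0.773 and 0.0545). The 32 patched-related receptors were split 16 and 16 (0.421). In tissue lists, 36 of 57 sperm genes lay above and 21 below, 5 of 6 vitellogenins above and 1 below, 14 of 29 neuron genes above and 15 below, 9 of 21 insulin-like peptides above and 12 below, and 14 of 35 cilia and glia genes above and 21 below (0.180, 0.099, 0.890, 0.677 and 0.741). In signalling lists, 20 of 27 Wnt genes lay above and 7 below, 10 of 17 BMP and body size genes above and 7 below, and 16 of 26 TOR and insulin genes above and 10 below (0.0572, 0.350 and 0.132). In stress lists, 20 of 24 ER stress genes lay above and 4 below, 12 of 21 heat shock genes above and 9 below, 9 of 20 mitochondrial stress genes above and 11 below, and 16 of 33 DAF-16-linked longevity genes above and 17 below (0.0545, 0.999, 0.297 and 0.850). For defence genes, 84 of 173 innate immunity genes lay above and 89 below, and 12 of 33 epidermal antimicrobial peptides above and 21 below (0.967 and 0.180). In metabolic lists, 17 of 25 fatty acid synthesis genes lay above and 8 below, 12 of 26 peroxisome and ether lipid genes above and 14 below, and 26 of 67 respiratory chain genes above and 41 below (0.234, 0.645 and 0.220). Of 82 ribosomal protein genes 59 lay above and 23 below, and of 42 histone genes 20 above and 22 below (0.180 and 0.967). The median, mean and test differed in sign for patched-related receptors, peroxisome and ether lipid, oxidative and xenobiotic, fasting-induced, DAF-16-linked, histone, innate immunity and heat shock genes. Adjusted over the list alone, edgeR called 1 gene each in the mitochondrial stress, DAF-16-linked and heat shock lists and 0 over all genes tested.

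Cuticle and hedgehog-related genes also varied strongly between libraries of the same label. Furrow collagens differed by -1.23 on the log2 scale (median) between EV replicates 3 and 1 and by -1.44 between grd-1 RNAi replicates 3 and 1. Other body-shape collagens differed by 0.91 and 0.74 in the same comparisons. The first principal component of log2 CPM held 45.5% of the variance, and its scores overlapped between the groups, from -25.4 to 37.3 in EV and from -28.9 to 18.8 in the libraries labelled grd-1 RNAi. The second held 22.1% and separated the groups, at -30.2, -7.35 and -8.10 in EV replicates 1, 2 and 3 against 14.7, 16.3 and 14.7 in the labelled libraries. EV replicate 1, the lowest on it, is also the library with an RNA integrity number of 8.3, against 10 in the others. RNA integrity was not tested for this component.

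**Figure D4:**
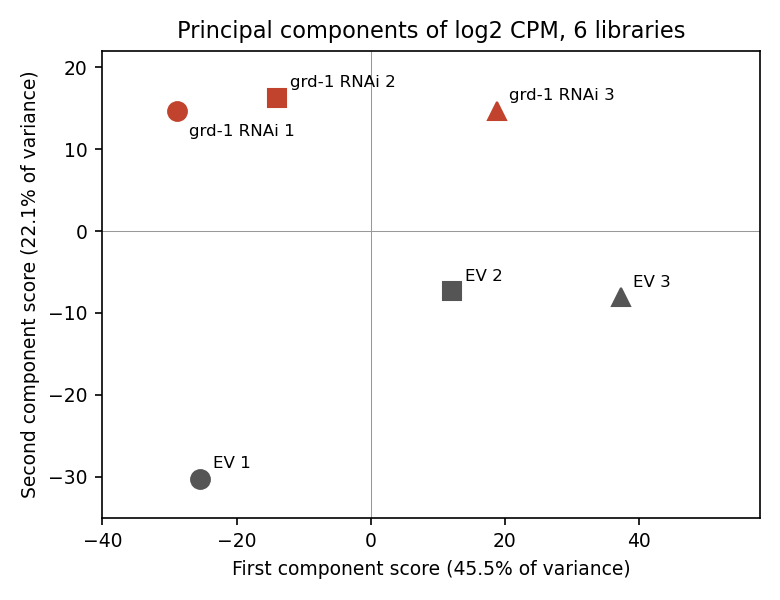
Scores of the 6 libraries on the first component (x axis, 45.5% of the variance) and second component (y axis, 22.1%) of log2 CPM, with EV in grey, libraries labelled grd-1 RNAi in red, and replicate numbers beside the points. The groups overlap on the x axis and are apart on the y axis, where EV replicate 1 lies lowest at -30.2.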

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

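Single transcripts of grd-1 in the deposited Salmon tables, which the gene comparison used only as a sum, reached levels above all EV libraries, R08B4.1a.1 in 3 and R08B4.1a.2 and R08B4.1b.1 in 1 of the 3 libraries labelled grd-1 RNAi. The tests of explanations in this part were chosen after the results were seen. Transcript R08B4.1a.1 was at 7.88, 8.93 and 5.37 TPM in labelled replicates 1, 2 and 3, where the highest EV library had 1.43 TPM. Transcript R08B4.1b.1 was at 0.550, 0.315 and 2.61 TPM, where the highest EV library had 0.767 TPM. Transcript R08B4.1a.2 was at 5.62 TPM, or 642 estimated counts, in grd-1 RNAi replicate 1 and was listed at 0 in the other 5 libraries, and R08B4.1b.2 was listed at 0 in all 6. The split of counts between these transcripts also varied within EV, where R08B4.1a.1 held 64.2% to 100% of the grd-1 counts.

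The grd-1 level was 6.49-fold higher in the libraries labelled grd-1 RNAi, in 3 of 3 libraries, and it was the largest rise among 11997 genes at a mean CPM of at least 1, where the next was 2.29 on the log2 scale. An exchange of 1 library of each group is argued against, since the lowest labelled library had 3.56 times the grd-1 CPM of the highest EV library, with no library out of place. Reads from the fed double-stranded RNA may add to the count and cannot be told apart from mRNA here. The libraries were poly(A)-selected, but how much fed RNA passed this step was not measured. A fed fragment would be expected to shift the share of counts on R08B4.1a.1 only if it covered sequence that the transcripts do not share. That share lay outside the EV range of 64.2% to 100% in 1 of the 3 labelled libraries, at 56.3%. The transcripts are 3723 to 3886 bases long, and a fragment within exons common to all of them would leave the share alone. The share thus could not decide whether fed RNA was counted. An exchange of the labels of all 6 libraries also cannot be told apart, since 0 libraries lay nearer to the other group's mean and no other value in these tables bears on it, and a true rise of grd-1 mRNA stays open, as untested. The titles of the labelled libraries speak of grd-1 control RNAi, while their treatment label reads grd-1 RNAi from hatch to L3.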

How the results depend on the processing

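The transcript length offset, DESeq2 with a library left out and Fisher's test on the DESeq2 calls were chosen after seeing the data. The grd-1 level kept its direction and an unadjusted p under 0.05 under every alternative run for it, from 2.40 to 2.94 on the log2 scale with a library left out. Its adjusted p over all genes was past the threshold with DESeq2, without a filter, in the blocked fit and without grd-1 RNAi replicate 3 (0.0206), and ranged from 6.77e-19 with DESeq2 to 0.757 without grd-1 RNAi replicate 2. The edgeR count of 0 became 5 (2 higher, 3 lower) without a filter and 79 with DESeq2, stayed 0 with limma-voom, and ran from 0 to 1 with a library left out. DESeq2 called 34 to 109 genes with a library left out, of which 31 to 58 were among the 79, and 16 of the 44 named DESeq2 genes kept their call in all 6 such fits. DESeq2 also ran without the filter on low counts, and the cause of the difference between tools was not tested. The 13 lists became 0 with an estimated correlation and 0 with fry (smallest adjusted p 0.112), 2 by Fisher's exact test on the DESeq2 calls, and 10 to 18 with a library left out (5 to 15 higher, 3 to 6 lower). The planned Fisher test on edgeR calls had no call to count. With the replicate number as a block edgeR called 416 genes (99 higher, 317 lower), all 79 DESeq2 genes and nhr-23 (0.50, adjusted p = 0.0168) among them. It called 14 lists, with 11 of the 13 among them and pharynx (0.0602) and ribosome biogenesis (0.0525) not. Under the other alternatives nhr-23 did not pass the threshold, with adjusted p-values of up to 0.968. Whether the numbers pair the libraries is not stated. Same-numbered libraries had correlated deviations of 0.40, -0.13 and 0.59, and EV replicate 2 correlated best with grd-1 RNAi replicate 3, at 0.07. Of 1005 values for 63 named genes under other settings, 94 newly passed the threshold (43 with DESeq2, 47 with the block, 4 without a filter), and 7 changed sign, in lin-42, lin-29, mlt-10 and nlp-66. No scaling moved the median of all genes by as much as 0.1. At this depth 18754 of 21982 genes could be tested without the filter and 13274 with it.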

Other observations

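The heme-responsive genes hrg-1, hrg-3, hrg-4 and hrg-7 were lower, and pud-1.2, pud-3 and pud-4 higher, in the libraries labelled grd-1 RNAi past the DESeq2 threshold and not that of edgeR. Tests in this part were chosen after the results were seen, except the counts over other splits of the libraries. The secreted heme transport protein gene hrg-3 had 8.32 ± 5.30 CPM in EV and 1.79 ± 0.195 CPM in the labelled libraries (SD, n = 3), a log2 fold change of -2.22 (SE 0.424), and -1.57 without EV replicate 2. The heme transporter genes hrg-1 and hrg-4 had -0.88 (SE 0.212) and -0.73 (SE 0.158), and hrg-7, an aspartic protease homologue that signals heme status between tissues, had -0.71 (SE 0.162). Of the 6 DESeq2 fits with a library left out, 1 called hrg-1, 1 called hrg-4, 2 called hrg-7 and 6 called hrg-3. Gene lists were then written around such genes, so a test of whether these lists moved would run on genes chosen for their values, and none is given. All 9 heme transport and heme-responsive genes lay below 0, with a median of -0.71, and 8 of 9 did without EV replicate 1 or grd-1 RNAi replicate 3. The groups did not overlap for hrg-1, hrg-2, hrg-3, hrg-4 and hrg-7. They overlapped for mrp-5, hrg-6, hrg-9 and hrg-10, at -0.07, -0.11, -0.40 and -0.22. All 4 tested pud genes lay above 0, with a median of 0.90. Of these, pud-1.2 had 0.78 (SE 0.168) and pud-2.2 had 0.61 (SE 0.221), and both have near-identical copies that share reads. Of 5 propionate shunt genes 4 lay below 0, with a median of -0.33, acdh-1 having the largest change at -1.26, and of 9 transsulfuration and sulfide genes 5 lay above 0 and 4 below, with a median of 0.02.

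Part of the 79 DESeq2 calls lay close together on the chromosomes. Apart from grd-1, 23 of 78 lay within 10 kb of another called gene, where 10000 random lists of tested genes matched on expression had a median of 2 and at most 13 (one-sided permutation p = 1e-04, the smallest they can give). The random lists drew genes independently of each other. Neighbours that vary together for any reason would also exceed them, so the excess does not bear on the label. On chromosome V, F22B8.4, F22B8.7, str-7, cth-1 and argk-1, all lower in the labelled libraries, lie between 16086572 and 16105952, and cyp-35A3, K09D9.1, C49G7.7, C49G7.10 and irg-2 between 4022609 and 4043601, where cyp-35A3 was higher in the labelled libraries and the others were lower. The other neighbours shared a direction within each group. They were pud-1.2 with pud-3 and pud-4, pals-23 with pals-24, ugt-43 with ugt-44, F18E3.12 with F18E3.13, C17H12.6 with H20E11.2 (-0.85 and -1.59), and T05E12.6 with srh-237 (-0.86 and -1.17). For the pud, pals, ugt and F18E3 genes, reads shared between members were not ruled out.

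The lower values of the 9 heme-responsive genes in the libraries labelled grd-1 RNAi, a pattern noticed in these data, were weighed against larval timing, RNA quality and food. Position on the first component did not account for the measured difference. Its slope within groups predicts a mean difference of -0.00631 (SE 0.0523) where -0.673 (SE 0.131) was measured. This component was not shown to track timing alone, and the second component, which separates the groups, was not used. A difference in larval timing between the groups is thus not excluded. The list was written around genes noticed for their low values. The measured difference may thus be overstated, and its SE does not cover that choice. Lower RNA integrity of EV replicate 1 is argued against, since without that library the difference was -0.765. Different bacterial food in the groups, which may change the heme supply, cannot be told apart from the label, because 0 bacterial treatments were given to libraries of both groups. An effect of the grd-1 clone itself stays open, as untested.

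The spread of the libraries along the first component may reflect small differences in larval timing at collection. The mean absolute loading of 256 molting and cuticle genes was 0.0137, above all 10000 expression-matched random lists (percentile 100, highest 0.00755). The random lists were matched on expression and not on variance. Any list of genes that vary strongly together would rank high, so the loading does not single out timing. RNA integrity is argued against as its cause, since grd-1 RNAi replicate 1, with an integrity number of 10, lay at -28.93, beyond EV replicate 1 at -25.39. Depth is argued against as well, since EV replicates 1 and 3, the nearest in total count, lay 94.7% of the component's range apart. No biological explanation by group was tested for it, as the groups overlap on this component.

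There are 10 splits of the 6 libraries into groups of 3, too few for a share under 0.05. The edgeR count was 0 for the real split and at most 670 for another, and since any split reaches 0, all 10 splits gave as many by construction, which says nothing about chance. At an unadjusted p under 0.05 edgeR had 1139 genes for the real split and at most 3303 for another, with 3 splits giving as many, the real one included. For DESeq2 the counts were 79 and at most 1319, with 2 splits giving as many, which are the real one and 1 other, and the remaining 8 gave 0 to 2. For lists they were 13 and at most 18, with 5 giving as many, the real one included. The split with 670 and 1319 genes set EV replicate 1 and grd-1 RNAi replicates 1 and 2, which have scores below 0 on the first component, against the rest, and so points to a structure of the libraries other than the label.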
